A study of Mus musculus with 9 samples.

How the data were processed

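RNA was measured by sequencing in 9 subcutaneous tumours of the mouse line LLC (Lewis lung carcinoma), 3 tumours in each of 3 groups. Host mice were randomised to the groups once tumours were near 100 mm3, per the labels' protocols, so the replicates are separate tumours. Total RNA was made into libraries with a universal Illumina RNA kit, per the labels' protocols. The deposited count of each gene in each tumour is a whole number of reads or fragments, not normalised, per the file headers. The deposited FPKM values were made by the authors, and over 9070 genes they equalled the count divided by 1 constant per gene and by the column total, with a largest relative deviation of 2.7e-06. HISAT2 2.0.4, StringTie 1.3.3b and the genome build mm10 are named per the submitters' processing notes, which give no roles. The counting tool, the annotation release and the strand setting were not given in the sources used here. Counts of overlapping and antisense genes are therefore uncertain, and so are those of near-identical copies such as histocompatibility genes, haemoglobin genes, Ifit3 with Ifit3b, and processed pseudogenes (Gm6485, Tpi-rs11, Rpl37rt).

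The table held 34745 genes, of which 13060 had no count in any tumour. Of the gene IDs, 80.8% lay at the same locus in the mouse reference annotation used here (GENCODE M21, the same build). Coordinates are as the deposited table gives them. Of the gene names 27 were written like dates, so genes were followed by ID, and 57 symbols occurred for more than 1 ID. Column totals ran from 18.52 M to 21.51 M counts (M, mega). The median standard error of a log2 fold change was 0.138, which sets the precision of a single gene.

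Group, replicate and dose came from the labels, and the control group follows the treatment label (isotype), though its library titles say blank. Isotype and anti-PDL1 columns carry the title of their library, and BTZ+anti-PDL1 columns were matched by treatment label and replicate number. The design gives 3 comparisons, namely anti-PDL1 against isotype, BTZ+anti-PDL1 against anti-PDL1, and BTZ+anti-PDL1 against isotype. Genes were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood F test with robust dispersion, TMM scaling and 1 model of 3 group means over all 9 tumours (6 residual degrees of freedom). The edgeR function filterByExpr, with a minimum count of 10, left 14506 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. CPM values are scaled by TMM and given as mean ± SD over 3 tumours. Fold changes are given with the standard error (SE) implied by the F test, which is the absolute log2 fold change divided by the square root of F.

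The gene lists, 26 with 465 entries, were fixed beforehand, and 7 symbols stand in more than 1 list, among them Cxcl10, Ciita and Ccl5. They cover interferon and DNA-sensing pathways, antigen presentation, immune and stromal cell types, other tissues a subcutaneous tumour piece can hold, and proteasome, stress, growth and metabolic programmes. Lists with at least 3 measured genes were tested with camera in limma 3.58.1, two-sided, on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over 25 lists. The keratinocyte list had 2 measured genes of 14 and was not tested. Each list was also tested by camera with an estimated correlation and by fry, and its genes were adjusted over the list alone. A list score is the mean over its genes of log2 CPM minus the mean of the 9 tumours.

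Named genes follow a rule. It takes a panel of 18 genes tied to the series title. To these it adds the strongest called genes by direction, or the 5 with the smallest p where fewer pass. From each list it takes up to 4 members with the smallest p in that comparison, so these are not typical of their list. Genes in the top part needed a mean of 1 CPM, and predicted loci were left out. Called genes also needed group values that do not overlap (chance gives 10% of genes with 3 tumours against 3). Genes filled in by smallest p did not need this. Gm6485 is an exception, named because it was the only call of its comparison. The other exceptions (mt-Atp6, Rac1, Ppp6c and Ywhah as examples of a count pattern, Isg15 and Usp18 in a plot, Acta1, Ckm, Myh4 and Adipoq as markers, Xist and Y-linked genes) were chosen after their values were seen. In the panel, Sting1 and Cgas stand under the older symbols Tmem173 and Mb21d1. Ifnb1 was under the filter and was not tested in the main fit. The values of 1 panel gene are not reported here.

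The tests of the 3 comparisons, the lists, the naming rule and all other settings but 3 were set before the data were examined. Tests chosen later are named with the additional observations. The settings chosen beforehand were RLE scaling, no filter on low counts, only the 6 tumours compared, the replicate number as a block, leaving out each tumour, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with FPKM of at least 1 in at least 3 tumours, a log2 fold change of at least 1, and DESeq2 1.42.0. The other 3 were chosen after seeing the data, namely the skeletal muscle score as a covariate, leaving out genes whose counts fall on 2 levels, and leaving out the tumour of each group with the most skeletal muscle RNA.

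The pipeline was tested on simulated data for BTZ+anti-PDL1 against anti-PDL1, with 14506 genes, 200 changed genes per simulation and 10 simulations. It called 65.9% of 2-fold changes (659 of 1000) and 93.3% of 4-fold changes. With the type I interferon list raised 1.6-fold, the list was called in 10 of 10 simulations and on average 7.5 of its 30 genes were called singly. Counts were drawn independently for each gene, whereas the genes of this list had an estimated correlation of 0.527 in the tumours. The simulations therefore do not test how camera with its preset correlation behaves for correlated genes. False calls averaged 11.1 genes per simulation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.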

Results

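Gene expression was measured in 9 tumours grown from LLC cells under the skin of male C57BL/6 mice. LLC (Lewis lung carcinoma) is a mouse lung cancer line that grows in this strain without rejection. The groups, with 3 tumours each, had received an isotype control antibody (10 mg/kg), an antibody against PDL1 (10 mg/kg), or the same antibody together with BTZ (bortezomib, 0.5 mg/kg). PDL1 is a ligand that restrains T cells, and bortezomib blocks the catalytic core of the proteasome. The treatment label gives the control as isotype, while the titles of its 3 libraries call it blank, and the treatment label was followed. No group received BTZ alone, so an effect of BTZ without the antibody was not analysed here. The series title ties bortezomib to immunotherapy, STING signalling and interferon-gamma. Total counts (M, mega) were 19.2 M, 20.97 M and 18.78 M in the isotype tumours, 19.99 M, 19.68 M and 21.51 M in the anti-PDL1 tumours, and 19.76 M, 18.52 M and 19.15 M in the BTZ+anti-PDL1 tumours.

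Skeletal muscle RNA differed most between tumours and did so within every group. Acta1, the actin of skeletal muscle fibres, ran from 0.21 to 672 CPM, a 3200-fold range. The skeletal muscle score was 4.5 in isotype replicate 3, 3.28 in anti-PDL1 replicate 1 and 3.16 in BTZ+anti-PDL1 replicate 1, against -3.67 in isotype replicate 1 and -3.45 in BTZ+anti-PDL1 replicate 3. The first principal component of log2 CPM held 38.6% of the variance. Isotype replicate 2 stood apart in immune content, with a T cell score of -2.09 against -0.36 to 0.72 in the other 8 tumours. Every tumour expressed Y-linked genes (27.4 to 43.2 CPM over 4 genes) together with Xist (641 to 1020 CPM), the X-inactivation RNA of female cells. The hosts were male.

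**Figure D1:**
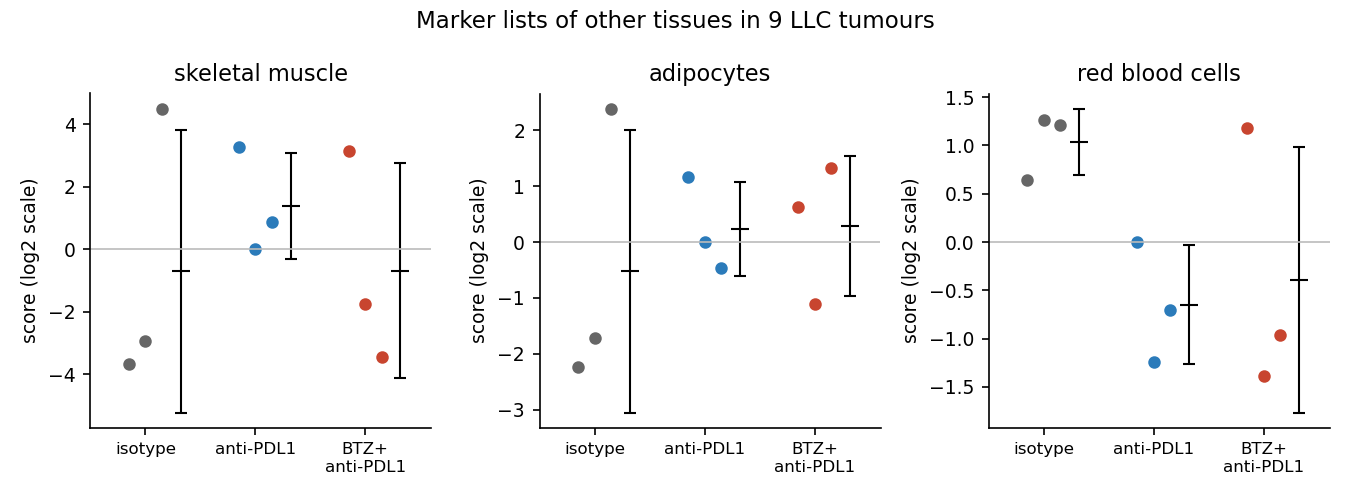
Scores of the skeletal muscle, adipocyte and red blood cell lists (mean log2 CPM of the list's genes minus the mean of the 9 tumours, vertical axis) in the 3 groups. Dots are tumours and bars show mean ± SD of 3. The muscle score ran from -3.67 to 4.5 within the isotype group alone, and the red blood cell score was higher in the 3 isotype tumours (0.642 to 1.26) than in the 3 anti-PDL1 tumours.

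The first comparison asked what the antibody against PDL1 changed by itself. Immune gene groups stood higher and red blood cell, stress and metabolic gene groups lower in the anti-PDL1 than in the isotype tumours. All 21 measured T cell genes had a higher value, with a median log2 fold change of 0.67 (1.59-fold), and 28 of 30 interferon-gamma response genes did, with a median of 0.59 (1.5-fold). Red blood cell genes were lower in 6 of 6, with a median of -1.73. Among single genes, Ski and Tmem70 fell. Camera called 20 of 25 lists, 12 higher and 8 lower, but with an estimated correlation it called 0 lists, the adjusted p being 0.436 for 16 of the 20 and at most 0.652. The fry test called 0 lists.

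Ski, a co-repressor that limits TGF-beta signalling (ENSMUSG00000029050, chromosome 4, 155154075 to 155222592, build mm10), had 182 ± 10.2 CPM in the isotype and 85.6 ± 2.79 CPM in the anti-PDL1 tumours (SD, n = 3 each). Its log2 fold change was -1.09 ± 0.0728 (SE, edgeR adjusted p = 0.000886). Tmem70, an assembly factor of the mitochondrial ATP synthase (ENSMUSG00000025940, chromosome 1, 16665207 to 16678275), went from 37.4 ± 2.03 to 19.3 ± 0.496 CPM (log2 fold change -0.96 ± 0.103, edgeR adjusted p = 0.0301). These were the 2 genes called of 14506. At an unadjusted p under 0.05 there were 921 genes (437 higher, 484 lower) where chance gives 725, and DESeq2 called 15 (8 higher, 7 lower). In both genes each tumour sat on 1 of 2 separate count levels, a pattern shared by 126 genes, for most of which the levels did not follow the groups; without those genes edgeR called 0 genes (916 at an unadjusted p under 0.05). The Tmem70 call was lost without any 1 of the 6 tumours compared or without BTZ+anti-PDL1 replicate 2 (adjusted p = 0.0506 to 0.275), at log2 fold changes of -0.99 to -0.92. Without the tumour of each group richest in muscle RNA, which leaves 6 tumours, both calls were lost (adjusted p = 0.0684 for Ski and 0.197 for Tmem70) at log2 fold changes of -1.13 and -0.93. The count of calls was 4 without isotype replicate 2 and 1 without anti-PDL1 replicate 1 or 2, all of them genes on 2 count levels.

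Further genes by smallest p did not pass in edgeR. Siglec1, a sialic acid receptor of macrophages, had a log2 fold change of 0.69 ± 0.116 (adjusted p = 0.551), and the cholesterol exporter Abcg1 had 0.61 ± 0.103. The circadian factor Clock had 0.55 ± 0.101, the fibril-associated collagen Col14a1 1.14 ± 0.207, and Tep1, a component of telomerase and vault particles, 0.31 ± 0.0578. On the lower side Tmem260 had -0.73 ± 0.107 (adjusted p = 0.284), Dnajc21 -0.38 ± 0.0802 and Tomm6, of the mitochondrial import pore, -0.74 ± 0.155. DESeq2 called each of these 8 except Dnajc21.

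Lymphocyte lists rose in the preset camera test. Zap70, the kinase behind the T cell receptor, had 1.03 ± 0.314 and the co-stimulatory receptor Cd28 0.99 ± 0.451, and the list's adjusted p was 2.13e-07 (adjusted p = 0.436 with an estimated correlation). In the cytotoxic and NK cell list 15 of 18 genes were higher (median 0.58, adjusted p = 0.000278, and adjusted p = 0.436 with an estimated correlation), including the granule protein Nkg7 (0.86 ± 0.368) and the NK receptor Klrb1c (0.58 ± 0.269). B and plasma cells had 4 of 6 higher (median 0.80, adjusted p = 0.038) and immune checkpoints 9 of 11 (median 0.47, adjusted p = 0.00214), again at adjusted p = 0.436 with an estimated correlation. No gene of these lists passed in edgeR, adjusted over the list alone or over all genes, and 1, 1, 0 and 0 of them had an unadjusted p under 0.05. These medians rested on the isotype tumours left in. Without isotype replicate 2 the T cell median was 0.27, the cytotoxic 0.34, the checkpoint 0.13 (call lost, adjusted p = 0.609) and the B cell 0.52 (call lost, adjusted p = 0.196). Without isotype replicate 3 they were 1.31, 1.07, 0.80 and 1.72. The B cell call was also lost without isotype replicate 1 (median 0.49, adjusted p = 0.817, with the test's direction turned), without any 1 anti-PDL1 tumour (0.117 to 0.482) without any 1 BTZ+anti-PDL1 tumour (0.204 to 0.327), without a count filter (0.175) and with the skeletal muscle score as a covariate (0.103). On FPKM values the cytotoxic call was lost (adjusted p = 0.0795 and 0.0825).

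Interferon and antigen presentation lists were called higher as well. The interferon-gamma response list had an adjusted p of 3.82e-08 (0.436 as the adjusted p with an estimated correlation), and Icam1, an adhesion molecule for leukocytes, and the class II activator Ciita had 0.74 ± 0.317 and 0.80 ± 0.421. For MHC class I 19 of 21 genes were higher (median 0.31, adjusted p = 6.3e-05), with the peptide trimmer Erap1 at 0.41 ± 0.11 and H2-D1 at 0.31 ± 0.185. For MHC class II all 11 were higher (median 0.41, adjusted p = 0.000909), among them the protease Ctss (0.41 ± 0.287). The cGAS-STING list had 15 of 19 higher (median 0.13, adjusted p = 0.00148) and the type I interferon-stimulated list 23 of 30 (median 0.18, adjusted p = 0.00324). With an estimated correlation the adjusted p was 0.436 for the first 3 of these 4 and 0.537 for the type I list. In none of the 5 did edgeR call a gene adjusted over the list alone, and each but MHC class II (0) held 1 gene at an unadjusted p under 0.05. Without isotype replicate 2 the interferon-gamma median was 0.22, and the other 4 calls were lost: MHC class I with a median of 0.096 (adjusted p = 0.131), MHC class II with 0.13 (0.27), cGAS-STING with 0.099 (0.103) and type I with 0.056 (0.658). Without isotype replicate 3 the medians were 1.06, 0.49, 0.87, 0.25 and 0.31 in the same order, and without anti-PDL1 replicate 1 the type I call was lost (adjusted p = 0.0781).

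Myeloid lists were called higher except neutrophils. Macrophage and monocyte genes were higher in 16 of 20 (median 0.33, adjusted p = 0.000581, and adjusted p = 0.436 with an estimated correlation), with the macrophage marker Adgre1 at 0.54 ± 0.219 and the monocyte marker Ly6c2 at 0.73 ± 0.279. Dendritic cell genes were higher in 11 of 13 (median 0.31, adjusted p = 0.00395, and adjusted p = 0.436 with an estimated correlation). In that list Siglech, of plasmacytoid dendritic cells, had 1.63 ± 0.519, while Fscn1, an actin bundler of mature dendritic cells, fell by 0.49 ± 0.12 on the log2 scale and was its 1 gene called by edgeR adjusted over the list alone (adjusted p = 0.0302, 0 over all genes). The macrophage list had 0 such genes, with 2 higher and 1 lower at an unadjusted p under 0.05. Both calls were lost without isotype replicate 2, with medians of 0.10 (adjusted p = 0.131) and 0.13 (adjusted p = 0.27), and the medians were 0.58 and 0.60 without isotype replicate 3. The dendritic call was also lost on FPKM values (adjusted p = 0.14 and 0.16). Neutrophil genes were not called (5 of 8 lower, adjusted p = 0.546), and their median of -0.062 and mean of 0.079 differed in sign. They were called higher without isotype replicate 3 (median 0.31, adjusted p = 0.0363) or the muscle-rich tumours (0.00684), against an adjusted p of 0.834 with an estimated correlation over all 9 tumours. With 1 tumour left out the median ran from -0.21 (without anti-PDL1 replicate 3) to that 0.31, and was above 0 without isotype replicate 3, anti-PDL1 replicate 1 or anti-PDL1 replicate 2.

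Lower lists began with red blood cells. Haemoglobin gene Hbb-bs had 79.5 ± 50.6 CPM in the isotype and 18.7 ± 6.01 CPM in the anti-PDL1 tumours, and the band 3 anion exchanger Slc4a1 had a log2 fold change of -2.03 ± 0.867. That list fell in the preset test (adjusted p = 4.99e-05, and adjusted p = 0.436 with an estimated correlation), though 0 of its genes passed in edgeR adjusted over the list alone and 2 had an unadjusted p under 0.05. Proteasome subunits were lower in 30 of 32 genes by little (median -0.076, adjusted p = 9.33e-05), for example Psma7 at -0.15 ± 0.0585. Unfolded protein and integrated stress response genes were lower in 19 of 20 (median -0.23, adjusted p = 9.31e-05), with the stress regulators Atf4 and Ddit3 at -0.36 ± 0.095 and -0.39 ± 0.139. Heat shock genes were lower in 14 of 14 (median -0.22, adjusted p = 0.000689), with Hspb8 at -0.29 ± 0.0888 and Hspe1 at -0.32 ± 0.106, and oxidative phosphorylation genes in 19 of 21 (median -0.076, adjusted p = 0.00202), with Cox5a at -0.27 ± 0.106 and Cox7a2 at -0.22 ± 0.084. NF-kappaB and inflammatory cytokine genes were lower in 16 of 19 (median -0.27, adjusted p = 0.011). With an estimated correlation the adjusted p of these 5 was 0.436. In the 5 lists edgeR called 0 genes adjusted over the list alone or over all genes, and 1, 5, 2, 4 and 2 genes were lower at an unadjusted p under 0.05. Heat shock was lost without isotype replicate 2 (median -0.095, adjusted p = 0.103), and NF-kappaB without anti-PDL1 replicate 1 (median -0.15, adjusted p = 0.292) or the 3 muscle-rich tumours (0.468). Other medians moved by over 1.5 times, to -0.17 for NF-kappaB without isotype replicate 3, to -0.16 for the unfolded protein list without anti-PDL1 replicate 1, and to -0.043 for oxidative phosphorylation without isotype replicate 3.

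Endothelial genes were lower in 11 of 12 (median -0.23, adjusted p = 0.027, and adjusted p = 0.52 with an estimated correlation) and hypoxia and glycolysis genes in 16 of 17 (median -0.25, adjusted p = 0.011, and adjusted p = 0.541 with an estimated correlation). In edgeR 0 of their genes passed adjusted over the list alone, and 0 had an unadjusted p under 0.05. The endothelial call was lost without isotype replicate 2 (median -0.091, adjusted p = 0.658), isotype replicate 3 (-0.15, 0.0827), anti-PDL1 replicate 1 (median -0.16, adjusted p = 0.181) or anti-PDL1 replicate 2 (0.106), without the 3 muscle-rich tumours (0.345) and with the muscle score as a covariate (0.0512). Its median was -0.37 without isotype replicate 1. The hypoxia call was lost without isotype replicate 1 (0.11), isotype replicate 2 (median -0.0049, adjusted p = 0.896) or anti-PDL1 replicate 1 (median -0.16, adjusted p = 0.211) and with the covariate (0.586), and its median was -0.46 without isotype replicate 3.

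Skeletal muscle genes had a median log2 fold change of -1.05 and were lower in 16 of 17, yet camera called the list higher (adjusted p = 0.0323, and adjusted p = 0.652 with an estimated correlation), the mean score being -0.705 in the isotype and 1.39 in the anti-PDL1 tumours. Fold changes are taken from mean counts and camera from mean log2 values. Without isotype replicate 3 the median was 7.30. It was -1.63 without isotype replicate 1 (adjusted p = 0.836, call lost) or isotype replicate 2 (0.65, call lost), -2.51 without anti-PDL1 replicate 1 (0.421, call lost) and -0.58 without anti-PDL1 replicate 2. The call was also lost on FPKM values (adjusted p = 0.0832 and 0.402). With the muscle score as a covariate the list's direction turned (0.262). That score is made from the same genes, so the covariate fit cannot test this list. Adipocyte genes (median -0.91, mean -0.68) were placed higher by camera without a call (adjusted p = 0.315). Fibroblast (median 0.062, adjusted p = 0.172), cell cycle (median -0.0009, mean 0.0053, adjusted p = 0.833) and apoptosis and p53 lists (median 0.026, adjusted p = 0.339) were not called. The adipocyte median was -1.47 without isotype replicate 1 or 2, -1.46 without anti-PDL1 replicate 1 and -0.57 without anti-PDL1 replicate 3. The list was called higher without isotype replicate 3 (median 4.17, adjusted p = 4.1e-05) or the muscle-rich tumours (0.000462). The fibroblast list was called higher without anti-PDL1 replicate 1 (median 0.17, adjusted p = 0.0174) or the muscle-rich tumours (0.0461). With 1 tumour left out its median ran from -0.061 (without anti-PDL1 replicate 2) to that 0.17, and was also below 0 without isotype replicate 1 (-0.028). Cell cycle genes were called higher without anti-PDL1 replicate 1 (median 0.070, adjusted p = 0.0436) or the muscle-rich tumours (0.00684). Their median ran from -0.068 (without isotype replicate 1) to that 0.070, and was also above 0 without isotype replicate 2, isotype replicate 3 or BTZ+anti-PDL1 replicate 3. The apoptosis median ran from -0.054 (without anti-PDL1 replicate 1, where alone it was below 0) to 0.13 (without isotype replicate 2). Over all 9 tumours the adjusted p with an estimated correlation was 0.764 for adipocytes, 0.52 for fibroblasts and 0.955 for cell cycle genes. Of the keratinocyte genes, Dmkn had -0.29 ± 0.584 and Sbsn -0.13 ± 0.21.

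**Figure D2:**
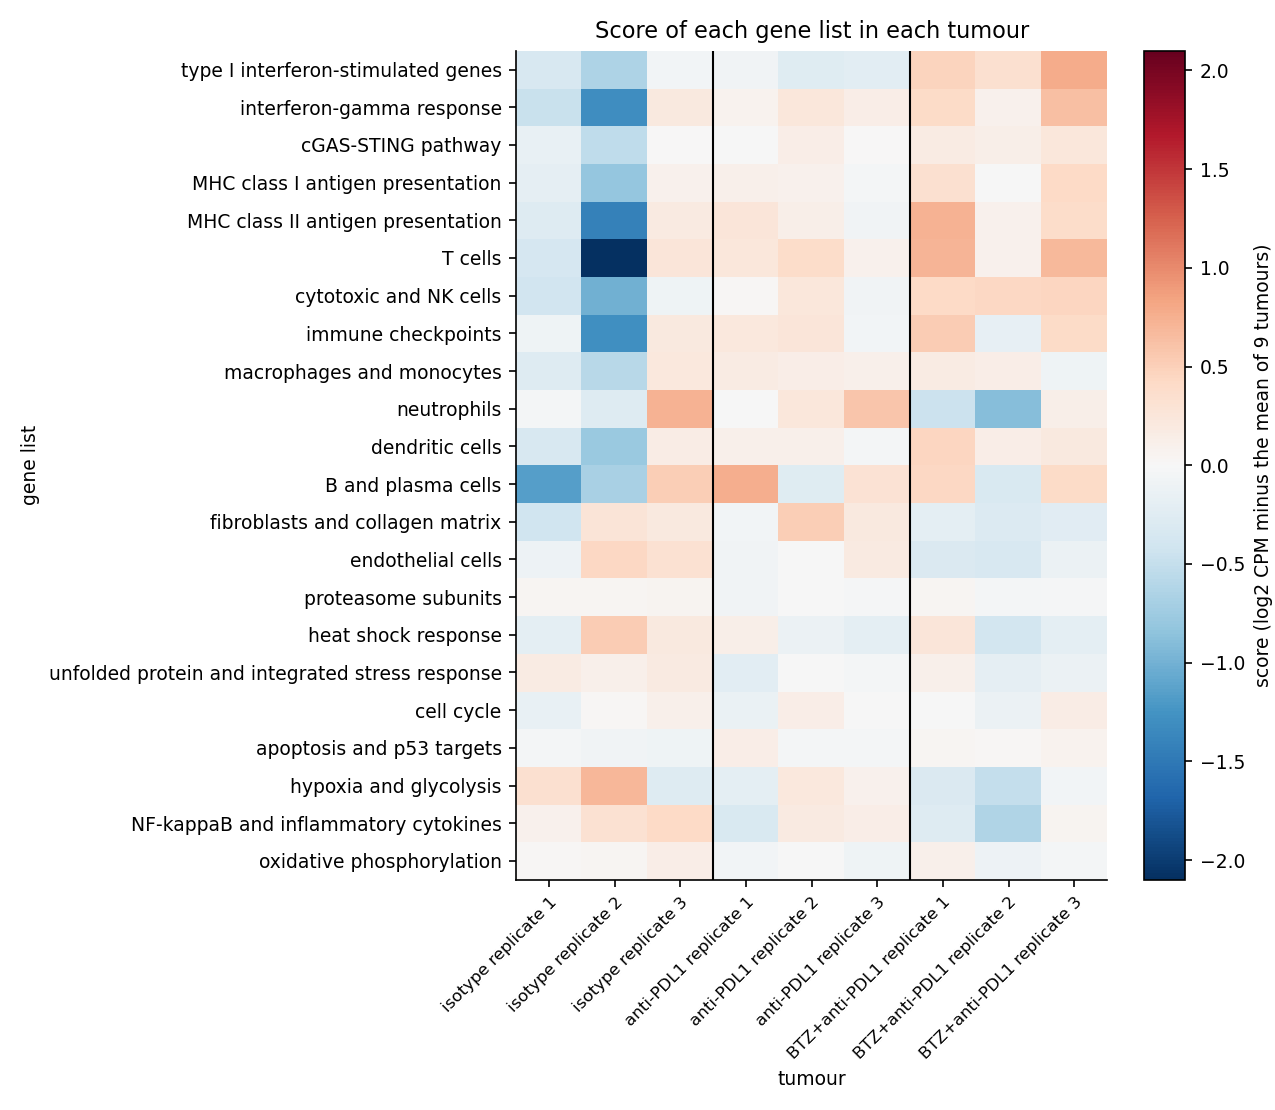
Heat map of the scores of 22 gene lists (vertical axis) in the 9 tumours (horizontal axis), where colour gives the mean log2 CPM of the list's genes minus the mean of the 9 tumours. The type I interferon list stood at 0.337 to 0.784 in the BTZ+anti-PDL1 tumours and from -0.641 to -0.0601 in the other 6, and isotype replicate 2 had the lowest T cell score, -2.09.

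The second comparison asked what BTZ added to the antibody. Type I interferon-stimulated genes were higher in the BTZ+anti-PDL1 than in the anti-PDL1 tumours in 30 of 30 cases, with a median log2 fold change of 0.71 (1.63-fold). Cytotoxic and NK cell genes were higher in 18 of 18 (median 0.33) and MHC class I genes in 18 of 21 (median 0.22). Neutrophil, fibroblast, endothelial, hypoxia and skeletal muscle genes were lower. Camera called these 8 of 25 lists, 3 higher and 5 lower. With an estimated correlation 0 lists were called (adjusted p = 0.496 to 0.92), and fry called 0. In edgeR Ski and Tmem70 rose.

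In the type I interferon list edgeR called 20 of 30 genes adjusted over the list alone, all higher, and 0 over all genes, while 23 had an unadjusted p under 0.05 and DESeq2 called 12 over all genes. Camera gave an adjusted p of 4.11e-26 (adjusted p = 0.496 with an estimated correlation). Ifit3, an interferon-induced protein that restrains viral RNA (ENSMUSG00000074896, chromosome 19, 34583531 to 34588731), had 16.4 ± 1.37 CPM in the anti-PDL1 and 33.7 ± 2.75 CPM in the BTZ+anti-PDL1 tumours (SD, n = 3 each). Its log2 fold change was 1.04 ± 0.149 (edgeR adjusted p = 0.177 over all genes, 0.00146 over the list alone). Irf7, the transcription factor that amplifies interferon production (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481), went from 17.2 ± 1.74 to 33.4 ± 6.01 CPM (0.96 ± 0.157, adjusted p = 0.293 over all genes, 0.00148 over the list alone). The mitochondrial nucleotide kinase Cmpk2 had 0.86 ± 0.142 and Ifit3b, whose sequence is close to that of Ifit3, 1.14 ± 0.196. The median was 1.63-fold in a group whose T cell list also stood at 0.37 and whose dendritic cell list stood at 0.32, while the neutrophil list stood at -0.67.

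**Figure D3:**
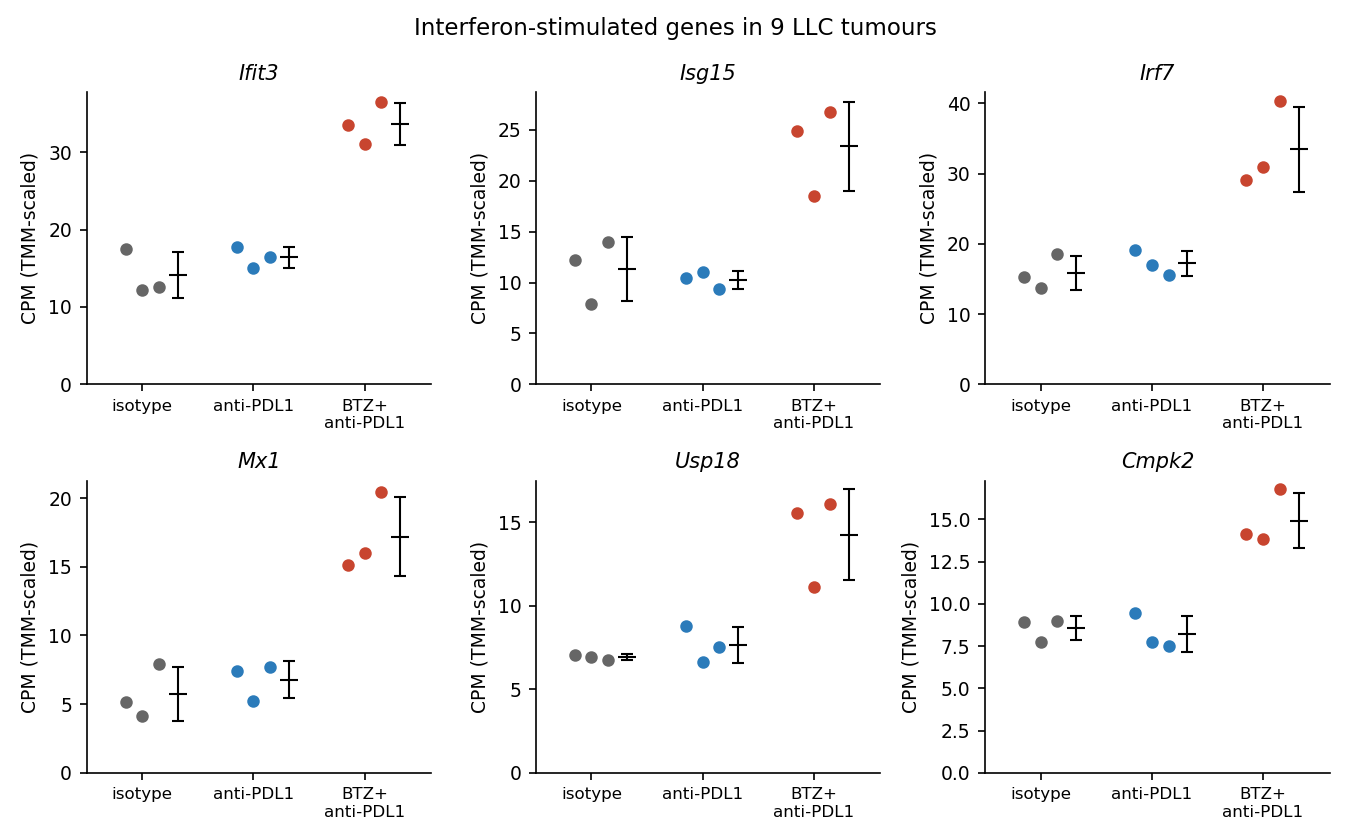
CPM (TMM-scaled, vertical axis) of Ifit3, Isg15, Irf7, Mx1, Usp18 and Cmpk2 in the 3 groups, with dots for tumours and bars for mean ± SD of 3. Ifit3 had 31.04 to 36.53 CPM in the 3 BTZ+anti-PDL1 tumours and at most 17.75 CPM in the other 6.

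Gzmb, a granule protease of killer lymphocytes, had 11.3 ± 2.07 CPM in the anti-PDL1 and 19.2 ± 2.03 CPM in the BTZ+anti-PDL1 tumours, a log2 fold change of 0.77 ± 0.187 (edgeR adjusted p = 0.606 over all genes). It was the 1 gene of the cytotoxic list called adjusted over the list alone (adjusted p = 0.0409) and the 1 with an unadjusted p under 0.05, and Gzma had 0.70 ± 0.333. The cytotoxic list rose in the preset test (adjusted p = 0.00297, and adjusted p = 0.721 with an estimated correlation). MHC class I genes did so with an adjusted p of 0.00515 (adjusted p = 0.92 with an estimated correlation). Among them H2-T23, a non-classical class I gene, had 0.54 ± 0.187 and the chaperone Pdia3 0.17 ± 0.0634, with 0 genes called by edgeR adjusted over the list alone and 2 at an unadjusted p under 0.05. The MHC class I call was lost without anti-PDL1 replicate 3 (adjusted p = 0.0766), BTZ+anti-PDL1 replicate 1 (0.0586) or BTZ+anti-PDL1 replicate 3 (0.18).

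On the lower side, neutrophil genes were lower in 8 of 8 (median -0.67, adjusted p = 0.000613, and adjusted p = 0.811 with an estimated correlation). S100a8 and S100a9, the calprotectin subunits of neutrophils, had -0.86 ± 0.311 and -1.05 ± 0.387, and Retnlg -1.34 ± 0.467. Fibroblast and collagen matrix genes were lower in 14 of 17 (median -0.44, adjusted p = 0.000427, and adjusted p = 0.496 with an estimated correlation), with the matrix proteins Postn at -0.94 ± 0.362 and Sparc at -0.49 ± 0.192. Endothelial genes were lower in 11 of 12 (median -0.31, adjusted p = 0.000257, and adjusted p = 0.747 with an estimated correlation), with Vwf, the platelet-binding factor, at -0.38 ± 0.117 and the junction cadherin Cdh5 at -0.41 ± 0.169. Hypoxia and glycolysis genes were lower in 17 of 17 (median -0.24, adjusted p = 0.00041, and adjusted p = 0.92 with an estimated correlation), with the glycolytic enzyme Aldoa at -0.22 ± 0.0743 and the angiogenic factor Vegfa at -0.42 ± 0.219. Of these 4 lists edgeR called 0 genes adjusted over the list alone or over all genes, and 3, 2, 2 and 1 genes were lower at an unadjusted p under 0.05. The neutrophil call was lost without BTZ+anti-PDL1 replicate 2 (adjusted p = 0.0513). The hypoxia median was -0.41 without anti-PDL1 replicate 1, -0.16 without anti-PDL1 replicate 2 and -0.14 without BTZ+anti-PDL1 replicate 2.

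Ski had 174 ± 12 CPM in the BTZ+anti-PDL1 tumours, a log2 fold change of 1.02 ± 0.0727 over the anti-PDL1 tumours (edgeR adjusted p = 0.0015), and Tmem70 had 36.3 ± 4.67 CPM (0.92 ± 0.103, adjusted p = 0.044). EdgeR called these 2 of 14506 genes, with 844 at an unadjusted p under 0.05 (457 higher, 387 lower), and DESeq2 called 60 (39 higher, 21 lower). Both lie among the genes on 2 count levels, without which edgeR called 0 genes (836 at an unadjusted p under 0.05). The Tmem70 call was lost without isotype replicate 3 (adjusted p = 0.081), any 1 anti-PDL1 tumour (0.133 to 0.205), BTZ+anti-PDL1 replicate 1 (0.0927) or BTZ+anti-PDL1 replicate 2 (0.119), at log2 fold changes of 0.81 to 0.95. Without the tumour of each group richest in muscle RNA, which leaves 6 tumours, both calls were lost (adjusted p = 0.163 for Ski and 0.334 for Tmem70) at log2 fold changes of 0.99 and 0.78. The count of calls was 7 without isotype replicate 1, 5 without isotype replicate 2 and 12 in a fit of the 6 tumours alone, and was 1 without isotype replicate 3, anti-PDL1 replicate 1, anti-PDL1 replicate 2 or BTZ+anti-PDL1 replicate 1. All calls without isotype replicate 2 were of genes on 2 count levels, and so were most without isotype replicate 1 or in the 6 tumours alone.

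Other genes with small p did not pass in edgeR but were called by DESeq2. Slfn4, an interferon-inducible gene of myeloid cells, had 1.02 ± 0.14 (edgeR adjusted p = 0.16). Col14a1 had -1.22 ± 0.208, the Wnt receptor Fzd1 -0.92 ± 0.165 and the adhesion molecule Ncam1 -0.68 ± 0.122. The zinc transporter Slc39a14 had -0.42 ± 0.0756 and the kinase Map3k1 -0.38 ± 0.0685, each at an edgeR adjusted p of 0.293.

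Skeletal muscle genes were lower in 14 of 17 (median -0.34, adjusted p = 0.0288, and adjusted p = 0.92 with an estimated correlation), with 0 genes called by edgeR and 0 at an unadjusted p under 0.05. That call was lost without anti-PDL1 replicate 1 (median 0.90, adjusted p = 0.373), BTZ+anti-PDL1 replicate 2 (0.12, adjusted p = 0.179) or BTZ+anti-PDL1 replicate 3 (0.15, adjusted p = 0.464), where the median turned. The median was -0.79 without anti-PDL1 replicate 2, -0.70 without anti-PDL1 replicate 3 and -4.92 without BTZ+anti-PDL1 replicate 1. On log2(FPKM + 1) the adjusted p was 0.0548. With the muscle score as a covariate the direction turned (0.499), but the score is made from the list's own genes and cannot test it.

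The remaining lists were not called over all 9 tumours, and several were called in other settings. Medians and adjusted p were 0.25 and 0.0786 for the interferon-gamma response, 0.076 and 0.0801 for cGAS-STING, 0.35 and 0.0786 for MHC class II, 0.37 and 0.143 for T cells, 0.32 and 0.0969 for dendritic cells, and 0.24 and 0.426 for immune checkpoints. Macrophage and monocyte genes had a median of 0.021 and a mean of -0.059 (adjusted p = 0.973), and within the list Ly6c2 had 0.77 ± 0.273 and the scavenger receptor Cd163 -1.89 ± 0.836. B and plasma cells had a median of -0.13 (adjusted p = 0.928), red blood cells 0.53 (0.624), adipocytes 0.074 (0.973), NF-kappaB -0.28 (0.195), cell cycle 0.014 (0.905) and apoptosis and p53 targets 0.052 (0.426). Proteasome subunits, the target complex of BTZ, had a median of 0.012 (adjusted p = 0.302), with Psma5 at 0.27 ± 0.0962. The unfolded protein list had 0.058 (0.624), oxidative phosphorylation 0.029 (0.426) and heat shock 0.0050 with a mean of -0.036 (0.629). Keratinocyte genes Dmkn and Sbsn had -0.48 ± 0.602 and -0.082 ± 0.21.

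Other settings added calls for 8 of these lists in the preset test. The estimated correlation was used over all 9 tumours only, where the adjusted p was 0.92 for each of the 8. The interferon-gamma response was called higher without isotype replicate 2 (adjusted p = 0.0027), isotype replicate 3 (0.0128), anti-PDL1 replicate 2 (0.0391) or BTZ+anti-PDL1 replicate 2 (0.0135). The same held in a fit of the 6 tumours alone (0.000289), with the muscle covariate (0.00235) and without a count filter (0.0318). MHC class II and T cell genes were called higher without isotype replicate 2 (0.00366 and 0.00814), isotype replicate 3 (0.0307 and 0.0386) or BTZ+anti-PDL1 replicate 2 (0.0247 and 0.0177), in the 6 tumours alone (0.00168 and 0.0028) and with the covariate (0.00127 and 0.00511). The cGAS-STING list was called higher without isotype replicate 2 (0.0203), isotype replicate 3 (0.0327) or anti-PDL1 replicate 2 (0.0277), in the 6 tumours alone (0.0192) and on FPKM values (0.0272 and 0.0358). Dendritic cell genes were called higher without isotype replicate 2 (0.0244) or BTZ+anti-PDL1 replicate 2 (0.042), in the 6 tumours alone (0.0207) and with the covariate (0.00301). NF-kappaB genes were called lower without anti-PDL1 replicate 1 (0.0171), BTZ+anti-PDL1 replicate 3 (0.0126) or the muscle-rich tumours (0.0253). Red blood cell genes turned and were called lower without BTZ+anti-PDL1 replicate 1 (median -0.80, adjusted p = 0.0187) or the muscle-rich tumours (0.0273). Oxidative phosphorylation genes were called higher without BTZ+anti-PDL1 replicate 2 (0.0448).

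With 1 tumour left out, several of these medians turned. The range was -0.0093 to 0.042 for proteasome subunits, -0.094 to 0.087 for heat shock and -0.039 to 0.12 for the unfolded protein list, in each from the fit without BTZ+anti-PDL1 replicate 1 to that without BTZ+anti-PDL1 replicate 3. It was -0.044 to 0.083 for oxidative phosphorylation, -0.80 to 0.98 for red blood cells and -0.30 to 0.13 for B cells, in each from the fit without BTZ+anti-PDL1 replicate 1 to that without BTZ+anti-PDL1 replicate 2. These 6 turned at BTZ+anti-PDL1 replicate 1 alone, except B cells, which turned without anti-PDL1 replicate 1 or BTZ+anti-PDL1 replicate 2. The macrophage median ran from -0.037 (without BTZ+anti-PDL1 replicate 2) to 0.094 (without anti-PDL1 replicate 1) and was also below 0 without anti-PDL1 replicate 2, anti-PDL1 replicate 3 or BTZ+anti-PDL1 replicate 1. The adipocyte median ran from -0.425 (without BTZ+anti-PDL1 replicate 3) to 0.60 (without anti-PDL1 replicate 1) and was also below 0 without anti-PDL1 replicate 2 or 3. The cell cycle median ran from -0.075 (without BTZ+anti-PDL1 replicate 3) to 0.068 (without anti-PDL1 replicate 2) and was also below 0 without anti-PDL1 replicate 1. Other medians kept their sign. They ran from 0.13 to 0.37 for the interferon-gamma response, 0.18 to 0.33 for dendritic cells and -0.53 to -0.14 for NF-kappaB, in each from the fit without BTZ+anti-PDL1 replicate 3 to that without BTZ+anti-PDL1 replicate 2. They ran from 0.13 to 0.495 for MHC class II and 0.21 to 0.555 for T cells, from the fit without BTZ+anti-PDL1 replicate 1 to that without BTZ+anti-PDL1 replicate 2. The checkpoint median ran from 0.073 (without BTZ+anti-PDL1 replicate 1) to 0.33 (without anti-PDL1 replicate 1), the cGAS-STING median from 0.058 (without BTZ+anti-PDL1 replicate 3) to 0.12 (without anti-PDL1 replicate 2), and the apoptosis median from 0.030 (without anti-PDL1 replicate 3) to 0.10 (without anti-PDL1 replicate 1).

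The third comparison set the combination against the isotype control. Type I interferon-stimulated genes were higher in 30 of 30 cases (median 0.83, 1.78-fold), T cell genes in 21 of 21 (median 1.01, 2.01-fold) and cytotoxic and NK cell genes in 18 of 18 (median 0.93, 1.91-fold). Endothelial genes were lower in 12 of 12 (median -0.49) and hypoxia and glycolysis genes in 17 of 17 (median -0.58). Camera called 20 of 25 lists, 10 higher and 10 lower. With an estimated correlation 0 were called (adjusted p = 0.209 to 0.464), and fry called 2, the type I interferon and the cytotoxic lists (adjusted p = 0.022 each). This comparison mixes the antibody and BTZ.

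For the type I interferon list camera gave an adjusted p of 6.41e-30 (adjusted p = 0.209 with an estimated correlation). In edgeR 26 of 30 genes were called adjusted over the list alone and 0 over all genes, 27 had an unadjusted p under 0.05, and DESeq2 called 18. Ifit3 had 1.26 ± 0.15 (edgeR adjusted p = 0.0511 over all genes), Irf7 1.08 ± 0.158 and Herc6, a ligase of the ISG15 system, 0.64 ± 0.102. Mx1, an antiviral GTPase, went from 5.75 ± 1.97 CPM in the isotype to 17.2 ± 2.85 CPM in the BTZ+anti-PDL1 tumours (SD, n = 3 each). In the cytotoxic list (adjusted p = 2.3e-09, and adjusted p = 0.209 with an estimated correlation) edgeR called 3 genes adjusted over the list alone, Ifng, Klrb1c and Gzmb, each at 0.0435, and 6 had an unadjusted p under 0.05. Klrb1c had 0.91 ± 0.268 and Nkg7 1.02 ± 0.368.

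Other immune lists were called higher. T cell genes had an adjusted p of 6.37e-10 (adjusted p = 0.291 with an estimated correlation), with the receptor chain Cd247 at 1.56 ± 0.476 and Zap70 at 1.07 ± 0.314. The interferon-gamma response was higher in 28 of 30 (median 0.90, adjusted p = 1.82e-11), with the GTPase Irgm1 at 0.85 ± 0.296, MHC class I in 20 of 21 (median 0.54, adjusted p = 5.74e-10), and MHC class II in 11 of 11 (median 0.83, adjusted p = 2.23e-06). The cGAS-STING list was higher in 14 of 19 (median 0.20, adjusted p = 1.87e-05), with the DNA sensors Ifi204 at 0.54 ± 0.0958 and Ifi203 at 0.80 ± 0.189, and dendritic cells in 11 of 13 (median 0.54, adjusted p = 0.000101), with Itgax at 0.60 ± 0.147 and the growth factor receptor Flt3 at 0.69 ± 0.249. With an estimated correlation the adjusted p of these 5 was 0.291. The genes of the cGAS-STING list did not rise alike. Mb21d1 had 1.06 ± 0.347 and Tmem173 0.21 ± 0.0744, while Irf3 had 0.018 ± 0.0952 and Tbk1 0.0014 ± 0.0765. Immune checkpoints were higher in 11 of 11 (median 0.56, adjusted p = 0.000343, and adjusted p = 0.297 with an estimated correlation), with Btla at 0.89 ± 0.3, and macrophages and monocytes in 16 of 20 (median 0.27, adjusted p = 0.00183, and adjusted p = 0.374 with an estimated correlation).

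Over these 8 lists edgeR called 0 genes over all genes. Adjusted over the list alone it called 5 of cGAS-STING, 1 of MHC class I (H2-T23, 0.81 ± 0.188), 1 of dendritic cells (Itgax) and 1 of macrophages (Ly6c2, 1.51 ± 0.28). The T cell, interferon-gamma, MHC class II and checkpoint lists had 0 such genes, with 7, 10, 2 and 2 at an unadjusted p under 0.05. Without isotype replicate 2 the medians were 0.43 for T cells, 0.56 for interferon-gamma, 0.27 for MHC class I, 0.48 for MHC class II, 0.31 for dendritic cells, 0.26 for checkpoints (call lost, adjusted p = 0.0976) and 0.051 for macrophages (call lost, adjusted p = 0.18). Without isotype replicate 3 they were 1.41 for interferon-gamma, 1.25 for MHC class II, 0.86 for dendritic cells, 0.96 for checkpoints and 0.47 for macrophages, and without BTZ+anti-PDL1 replicate 3 the checkpoint median was 0.37. B and plasma cells were higher in 6 of 6 without a call (median 0.52, adjusted p = 0.0542). Without isotype replicate 1 they were higher in 4 of 6 (median 0.19), and the median was 0.27 without BTZ+anti-PDL1 replicate 1 and 0.78 without BTZ+anti-PDL1 replicate 2. They were called higher without isotype replicate 3 (median 1.25, adjusted p = 0.00187) or the muscle-rich tumours (0.00516), in a fit of the 6 tumours alone (0.0494) and with the muscle covariate (0.0194), against an adjusted p of 0.374 with an estimated correlation over all 9 tumours.

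Among the lower lists, endothelial genes had an adjusted p of 7.75e-08 (adjusted p = 0.291 with an estimated correlation), and edgeR called 8 of 12 adjusted over the list alone, among them Cdh5 (-0.56 ± 0.169) and Vwf (-0.41 ± 0.117). Hypoxia and glycolysis genes had an adjusted p of 3.29e-08 (adjusted p = 0.291 with an estimated correlation), with Vegfa at -0.85 ± 0.22 and hexokinase Hk2 at -0.58 ± 0.186. NF-kappaB and inflammatory cytokine genes were lower in 15 of 19 (median -0.59, adjusted p = 0.000544, and adjusted p = 0.291 with an estimated correlation), with Ptgs2, the inducible cyclooxygenase, at -1.25 ± 0.305 and Il6 at -1.60 ± 0.618. Neutrophil genes were lower in 7 of 8 (median -0.40, adjusted p = 0.0072, and adjusted p = 0.374 with an estimated correlation), and edgeR called 3 adjusted over the list alone, among them S100a9 (-1.23 ± 0.388) and Retnlg (-1.54 ± 0.467). Fibroblast genes were lower in 12 of 17 (median -0.37, adjusted p = 0.0311, and adjusted p = 0.297 with an estimated correlation), with Fap at -0.86 ± 0.279. The hypoxia, NF-kappaB and fibroblast lists had 0 genes called adjusted over the list alone and 7, 5 and 3 lower at an unadjusted p under 0.05. Without isotype replicate 2 the hypoxia median was -0.33. The neutrophil call was lost without isotype replicate 3 (median 0.028, adjusted p = 0.385), BTZ+anti-PDL1 replicate 1 (0.0627) or BTZ+anti-PDL1 replicate 2 (median -0.19, adjusted p = 0.187), without the 3 muscle-rich tumours (0.516) and without a count filter (0.0728), and its median was -0.80 without BTZ+anti-PDL1 replicate 3. The fibroblast call was lost without isotype replicate 2 (0.104), isotype replicate 3 (0.0527), BTZ+anti-PDL1 replicate 1 (0.0547) or BTZ+anti-PDL1 replicate 3 (0.098), or without the muscle-rich tumours (0.0645).

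Stress and metabolic lists were also called lower. The unfolded protein and integrated stress response list was lower in 14 of 20 (median -0.15, adjusted p = 0.00237, and adjusted p = 0.291 with an estimated correlation), and edgeR called 2 genes adjusted over the list alone, the phosphatase subunit Ppp1r15a (-0.67 ± 0.151) and Atf4 (-0.37 ± 0.0951). Heat shock genes were lower in 13 of 14 (median -0.18, adjusted p = 0.00675, and adjusted p = 0.325 with an estimated correlation), red blood cell genes in 6 of 6 (median -1.06, adjusted p = 0.000544, and adjusted p = 0.297 with an estimated correlation) and proteasome subunits in 27 of 32 (median -0.053, adjusted p = 0.00907, and adjusted p = 0.374 with an estimated correlation). Oxidative phosphorylation genes were lower in 16 of 21 (median -0.053, adjusted p = 0.0378, and adjusted p = 0.464 with an estimated correlation). The last 4 lists had 0 genes called adjusted over the list alone, with 2, 0, 0 and 0 lower at an unadjusted p under 0.05.

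These calls rested on single tumours in part. The heat shock call was lost without isotype replicate 2 (median -0.11, adjusted p = 0.13) or BTZ+anti-PDL1 replicate 2 (-0.11, 0.0761). The proteasome call was lost without BTZ+anti-PDL1 replicate 2 (adjusted p = 0.0953) or BTZ+anti-PDL1 replicate 3 (median -0.034, adjusted p = 0.0993). The oxidative phosphorylation call was lost without isotype replicate 3 (adjusted p = 0.198), BTZ+anti-PDL1 replicate 2 (median -0.030, adjusted p = 0.516) or BTZ+anti-PDL1 replicate 3 (median -0.026, adjusted p = 0.113) and on FPKM values (0.0718 and 0.0762). Without BTZ+anti-PDL1 replicate 1 the medians were -0.32 for heat shock, -0.31 for unfolded protein, -0.15 for oxidative phosphorylation and -2.48 for red blood cells. Without BTZ+anti-PDL1 replicate 2 the unfolded protein median was -0.099 and the red blood cell median -0.66. Skeletal muscle (median -1.49, adjusted p = 0.798), adipocyte (median -0.67 but placed higher by camera, adjusted p = 0.311), cell cycle (median 0.027, adjusted p = 0.695) and apoptosis and p53 lists (median 0.10, adjusted p = 0.0886) were not called. Skeletal muscle was called higher without isotype replicate 3 (median 7.28, adjusted p = 0.00161) and lower without BTZ+anti-PDL1 replicate 1 (median -5.91, adjusted p = 0.0136). The adipocyte median was -1.24 without isotype replicate 1, -1.23 without isotype replicate 2 and -1.10 without BTZ+anti-PDL1 replicate 3. That list was called higher without isotype replicate 3 (median 4.63, adjusted p = 5.87e-05), BTZ+anti-PDL1 replicate 2 (median -0.16, adjusted p = 0.0429) or the muscle-rich tumours (0.000315). Over all 9 tumours the adjusted p with an estimated correlation was 0.948 for skeletal muscle and 0.769 for adipocytes. With 1 tumour left out the cell cycle median ran from -0.060 (without BTZ+anti-PDL1 replicate 3) to 0.086 (without BTZ+anti-PDL1 replicate 2) and was also below 0 without isotype replicate 1, and the apoptosis median ran from 0.065 (without isotype replicate 1) to 0.11 (without isotype replicate 2 or BTZ+anti-PDL1 replicate 2). The keratinocyte genes Dmkn and Sbsn had -0.77 ± 0.598 and -0.21 ± 0.21.

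Of single genes edgeR called 1, Gm6485, a transcribed processed pseudogene (ENSMUSG00000089999, chromosome 3, 104752727 to 104753165), which was named after its values were seen. It had 66.9 ± 3.3 CPM in the isotype, 51.8 ± 0.556 in the anti-PDL1 and 42 ± 1.55 in the BTZ+anti-PDL1 tumours and fell by 0.67 ± 0.0671 on the log2 scale (edgeR adjusted p = 0.0332). Its reads can be shared with its parent gene, so this value is uncertain. At an unadjusted p under 0.05 there were 1247 genes (641 higher, 606 lower), and DESeq2 called 111 (65 higher, 46 lower). The Gm6485 call was lost without isotype replicate 1 (adjusted p = 0.0789), anti-PDL1 replicate 2 or 3 (0.094 and 0.0972) or any 1 BTZ+anti-PDL1 tumour (0.0664 to 0.193), in a fit of the 6 tumours alone (0.143), with the muscle covariate (0.0779) and without the muscle-rich tumours (0.221). Its log2 fold change lay between -0.70 and -0.63 in all of these settings. The count of calls was 20 without isotype replicate 3, where Ifit3, Irf7, Mx1 and Slfn4 passed. It was 4 without isotype replicate 2, 3 without anti-PDL1 replicate 1, 2 without isotype replicate 1 and 0 without any 1 of the other 5 tumours. Of the calls without isotype replicate 2, all but Gm6485 were of genes on 2 count levels.

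The genes next in p did not pass in edgeR. Lgals3bp, a secreted galectin-binding protein, had 72.0 ± 4.49 CPM in the isotype and 149.6 ± 23.1 CPM in the BTZ+anti-PDL1 tumours (1.05 ± 0.135, edgeR adjusted p = 0.0684), Slfn4 had 1.07 ± 0.14 and the T cell adaptor Sh2d2a 1.5 ± 0.219. On the lower side Tmem260, also on 2 count levels, had -0.93 ± 0.107 (adjusted p = 0.0511), the neutrophil attractant Cxcl5 -2.37 ± 0.441 and the actin-binding protein Dbn1 -0.62 ± 0.116. The pseudogene Tpi-rs11 had -0.82 ± 0.116 and the retrogene Rpl37rt -0.38 ± 0.0671, and both can share reads with their parent genes. DESeq2 called each of these 8.

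Genes of the panel drawn from the series title were given whether or not they passed. EdgeR called 0 of its 17 tested genes over all genes in any comparison. Adjusted over the list alone, Gzmb passed for BTZ+anti-PDL1 against anti-PDL1 (adjusted p = 0.0386), and Ifng, Cxcl10 and Gzmb passed for BTZ+anti-PDL1 against isotype (0.0434 each). Ifng, the interferon-gamma gene, had 0.157 ± 0.138, 0.411 ± 0.133 and 0.863 ± 0.252 CPM in the isotype, anti-PDL1 and BTZ+anti-PDL1 tumours (SD, n = 3 each), a log2 fold change of 2.43 ± 0.708 for the last over the first. Its raw counts were 4, 0 and 5 in the isotype and 20, 19 and 11 in the BTZ+anti-PDL1 tumours, so this change rests on few counts. Cxcl10, a chemokine induced by interferons, had 34.9 ± 15.3, 46.2 ± 4.79 and 77.9 ± 18.8 CPM. DESeq2 called Gzmb for BTZ+anti-PDL1 against anti-PDL1 and Cxcl10 for BTZ+anti-PDL1 against isotype. Tmem173, the gene of STING, had 78.8 ± 7.08, 84.6 ± 2.58 and 91.1 ± 2.52 CPM, and Mb21d1, the gene of its upstream sensor cGAS, 1.67 ± 0.866, 3.3 ± 0.387 and 3.48 ± 0.772 CPM.

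For BTZ+anti-PDL1 against anti-PDL1 the log2 fold change was 0.11 ± 0.0744 for Tmem173, 0.075 ± 0.336 for Mb21d1, -0.043 ± 0.0764 for the kinase Tbk1 and 0.025 ± 0.0952 for the factor Irf3. It was 0.25 ± 0.18 for Irf1, 1.06 ± 0.627 for Ifng, 0.24 ± 0.738 for Cxcl9, 0.76 ± 0.321 for Cxcl10 and 0.11 ± 0.529 for Ccl5. It was -0.013 ± 0.267 for Cd274, which encodes PDL1, 0.11 ± 0.659 for the T cell co-receptor Cd8a, 0.31 ± 0.249 for the pore former Prf1, 0.32 ± 0.291 for H2-K1, 0.25 ± 0.197 for B2m and 0.011 ± 0.0894 for Psmb5, the proteasome subunit that BTZ binds. For BTZ+anti-PDL1 against isotype Tmem173 had 0.21 ± 0.0744, Mb21d1 1.06 ± 0.347, Irf1 0.53 ± 0.181 (adjusted p = 0.0538 over the list alone for each), Cd274 0.56 ± 0.27, Cxcl9 1.16 ± 0.752, Ccl5 1.02 ± 0.542, H2-K1 0.70 ± 0.292, B2m 0.43 ± 0.197 and Cd8a 0.74 ± 0.67. Prf1 had 0.23 ± 0.249, Tbk1 0.0014 ± 0.0765, Irf3 0.018 ± 0.0952 and Psmb5 -0.083 ± 0.0894. For anti-PDL1 against isotype Mb21d1 had 0.98 ± 0.347, Ifng 1.37 ± 0.741, Cxcl9 0.92 ± 0.749, Ccl5 0.91 ± 0.541, Cd8a 0.63 ± 0.67, Cd274 0.57 ± 0.269, Cxcl10 0.40 ± 0.323 and H2-K1 0.38 ± 0.292. Irf1 had 0.29 ± 0.181, B2m 0.18 ± 0.197, Tmem173 0.10 ± 0.0744, Tbk1 0.044 ± 0.0764, Irf3 -0.0066 ± 0.0952, Prf1 -0.074 ± 0.25, Gzmb -0.086 ± 0.187 and Psmb5 -0.093 ± 0.0894. Cd8a, Ccl5 and Cxcl9 had 0.396, 1.089 and 5.345 CPM in isotype replicate 2. They had 5.457, 6.402 and 35.31 CPM in isotype replicate 1, and 4.809, 6.743 and 69.47 CPM in isotype replicate 3. Their values in both comparisons against isotype therefore rest in part on isotype replicate 2. Ifnb1 had 8 counts in all 9 tumours together and was left out of the main tests by the count filter. So few counts measure it poorly at this depth.

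**Figure D4:**
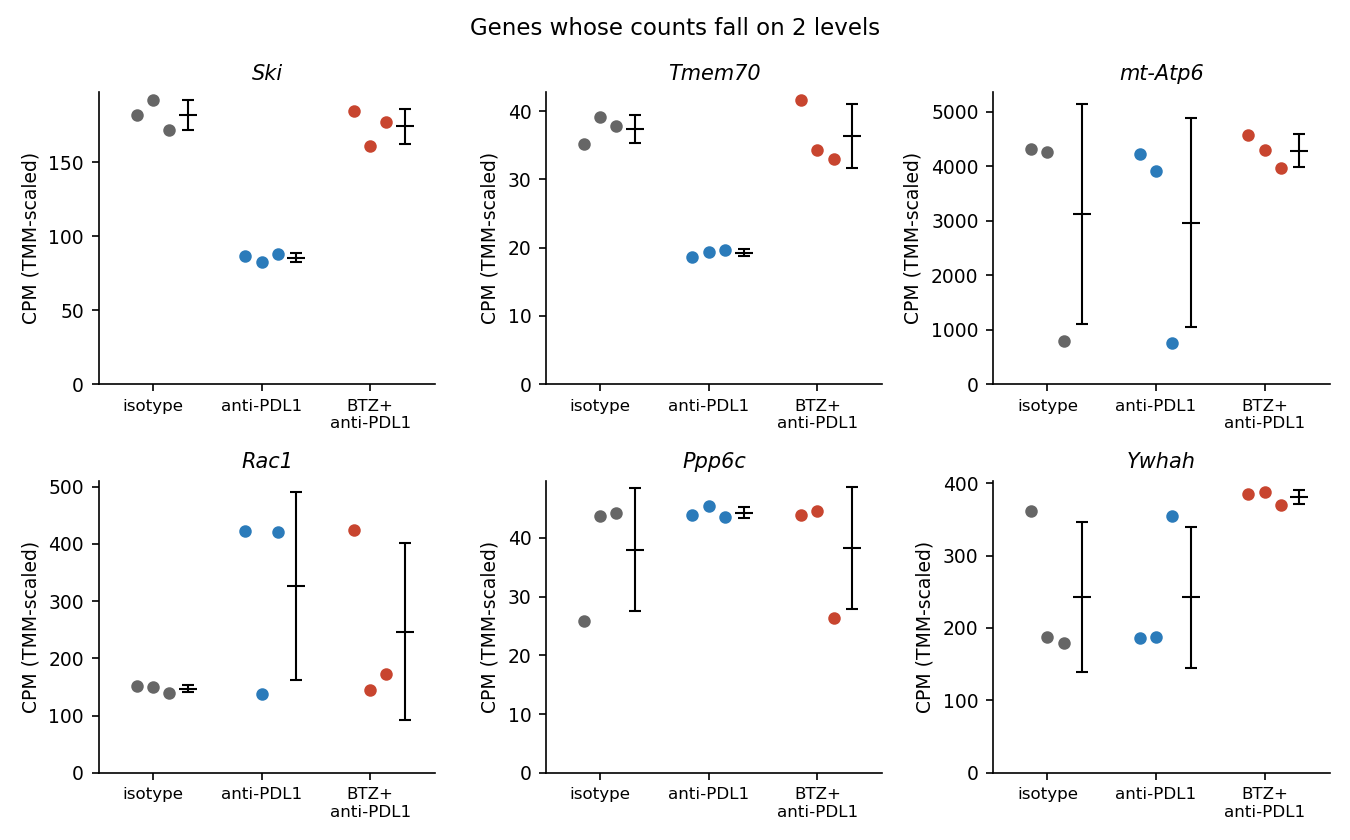
CPM (TMM-scaled, vertical axis) of Ski, Tmem70, mt-Atp6, Rac1, Ppp6c and Ywhah in the 3 groups, with dots for tumours and bars for mean ± SD of 3. Each gene has 2 separate levels, which follow a group for Ski and Tmem70 (3 anti-PDL1 tumours on the lower level) and not for the other 4, as for mt-Atp6 with 789.2 and 761.3 CPM in isotype replicate 3 and anti-PDL1 replicate 3 against 3905 to 4576 CPM elsewhere.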

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

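Of the alternatives below, the skeletal muscle score as a covariate and both fits without 2-level genes or without the most muscle-rich tumour of each group were chosen after seeing the data, and the others were planned. RLE scaling changed no count of calls. Counts of called genes are given for anti-PDL1 against isotype (main value 2), BTZ+anti-PDL1 against anti-PDL1 (2) and BTZ+anti-PDL1 against isotype (1). DESeq2 gave 15, 60 and 111, and gave no adjusted p for 58, 1731 and 58 genes. With no filter beyond a total of 1 count the later pair of comparisons gave 4 (with Ifit3 and Slfn4 added) and 6. A fit of only the 6 tumours compared, which has fewer samples, gave 12 and 0 for them. With a log2 fold change of at least 1 as well the counts were 1, 1 and 0. Both FPKM settings gave 3 for BTZ+anti-PDL1 against isotype, and the muscle covariate gave 0 there. Without the genes on 2 levels the first pair of comparisons gave 0 and 0, since Ski and Tmem70 are among those left out. Without the tumour of each group richest in skeletal muscle RNA, which leaves 6 tumours, the counts were 0, 0 and 0, with 1092, 735 and 1416 genes at an unadjusted p under 0.05. Leaving out 1 tumour gave 1 to 4, 1 to 7 and 0 to 20 genes. Of lists, leaving out 1 tumour gave 8 to 21 (main value 20), 7 to 13 (main value 8) and 16 to 21 (main value 20), and only the 6 tumours compared gave 13 for BTZ+anti-PDL1 against anti-PDL1. With an estimated correlation camera called 0, 0 and 0 lists, and fry called 0, 0 and 2. The 2 camera runs differed only in how the correlation between genes was set, so that setting accounts for the list calls lost between them. It was preset at 0.01, while the estimates ran from 0.0407 (apoptosis and p53 targets) to 0.973 (skeletal muscle). The cause of the other differences was not tested. Named genes kept direction and side of the threshold in 880 of 909, 785 of 827 and 946 of 1005 values. The call was lost in 10, 9 and 10 values and gained in 7, 16 and 41. The direction turned in 12, 17 and 8 values, in 3, 5 and 3 genes that were not called, with main values from -0.0858 to 0.234. For these the cause was not tested.

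Turned values were as follows. For anti-PDL1 against isotype Irf3 was 0.00409 on log2(FPKM + 1), 0.00445 on log2(FPKM + 0.1) and 0.0376 without the muscle-rich tumours, Gzmb was 0.202 without these tumours, and Prf1 was 0.145 with the muscle covariate. Leaving out 1 tumour gave -0.0611 to 0.053 for Irf3, -0.232 to 0.0579 for Gzmb and -0.329 to 0.132 for Prf1. For BTZ+anti-PDL1 against anti-PDL1 Cd274 was 0.0421 with the covariate, and without the muscle-rich tumours Irf3 was -0.0328, Ccl5 -0.0417 and Psmb5 -0.0158. Leaving out 1 tumour gave -0.0823 to 0.218 for Ccl5, -0.269 to 0.128 for Cd274, -0.0478 to 0.0744 for Irf3, -0.108 to 0.209 for Mb21d1 and -0.0551 to 0.0598 for Psmb5. For BTZ+anti-PDL1 against isotype Tbk1 was -0.00134 with RLE scaling and -0.00136 in DESeq2. Leaving out 1 tumour gave -0.0421 to 0.0743 for Tbk1, -0.0542 to 0.0778 for Irf3 and -0.0215 to 0.44 for Prf1.

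Replicate numbers are shared by the groups, and the values showed no clear pairing of tumours by number. The first principal component followed the skeletal muscle score with an absolute r of 0.98. A pairing hidden by muscle content therefore cannot be excluded. Same-numbered tumours deviated together with r from -0.43 to 0.39 over 9 pairs, 2 of the pairs were over 0.1, and 1 of 9 tumours correlated best with its own number. With the replicate number as a block the gene counts were 1, 1 and 0, where Tmem70 and Gm6485 were no longer called, and the oxidative phosphorylation list of BTZ+anti-PDL1 against isotype had an adjusted p of 0.0501. With the block camera called further lists higher, namely the interferon-gamma response (adjusted p = 0.0306) and MHC class II (0.0422) for BTZ+anti-PDL1 against anti-PDL1, and B and plasma cells (0.0308) for BTZ+anti-PDL1 against isotype. Without the block these had an adjusted p of 0.92, 0.92 and 0.374 with an estimated correlation. Depth limits the lowly counted genes of the panel, since Ifnb1 had 8 counts in all and Ifng had means of 0.157 to 0.863 CPM.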

Other observations

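The exact permutation tests of list scores, the rule for 2-level genes, the test of overlap at Ski and Tmem70, and the tests of interferon genes and T cells were chosen after the results were seen. The tests of locus overlap over all 2-level genes and 3' UTR length were set before their values were computed but after the genes had been named.

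Among the 25 list scores, 3 separated the BTZ+anti-PDL1 tumours from the other 6. The type I interferon score was higher by 0.792 (exact permutation p = 0.0119, the smallest that 84 sets can give, adjusted p = 0.264 over 25 lists), the cytotoxic and NK cell score by 0.653 (exact permutation p = 0.0476), and the endothelial score differed by -0.378 (exact permutation p = 0.0238). None passed the adjustment, which 84 sets and 25 lists put out of reach unless several lists share that smallest p. Y-linked genes were detected in all 9 tumours (27.4 to 43.2 CPM over 4 genes) beside Xist at 641 to 1020 CPM in male hosts, and neither the sex of the LLC cells nor the share of host cells was tested.

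Ski and Tmem70 were lower in the 3 anti-PDL1 tumours than in the other 6. Counts fell on 2 separate levels in 126 of 9828 genes against at most 30 in simulated counts. Of 41 such genes with 3 tumours against 6, 3 had a treatment group as the 3 (Ski, Tmem70 and Tmem260) where chance gives 1.46 (exact binomial p = 0.18). With so few matches expected, and with Ski and Tmem70, which prompted the test, among the matches, this test cannot decide. The excess of 2-level genes over simulated counts leaves it possible that a count artefact that ignores the groups accounts for both genes. The 126 genes had a median 3' UTR of 2456.5 nucleotides against 1442 in matched sets (permutation p = 1e-04, the smallest that 10000 sets can give), which is consistent with 3' ends counted in some tumours only, though Tmem70 has 853. Of Ski and Tmem70, 0 overlap another gene of the deposited table, which argues against reads assigned to an overlapping gene for both, while for the 126 genes overlap with another tested gene (29.4% against 23%, permutation p = 0.071) cannot be told apart from chance, and an effect of the antibody on Ski and Tmem70 stays open.

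Type I interferon-stimulated genes were higher in the BTZ+anti-PDL1 than in the anti-PDL1 tumours. With the skeletal muscle score as a covariate their median log2 fold change was 0.754, which argues against muscle tissue as the whole cause. A higher share of immune cells of every kind was weighed by the medians of immune lists. These were uneven, at -0.667 for neutrophils beside 0.371 for T cells and 0.021 for macrophages and monocytes. The immune test was first run on the highest of these medians and then on the lowest, after they were seen, so it cannot decide. For neutrophils camera gave an adjusted p of 0.811 with an estimated correlation. In the preset test it was 0.0513 without BTZ+anti-PDL1 replicate 2. More cells of particular kinds, such as lymphocytes or Ly6c2-expressing monocytes, and a response to BTZ within cells may each contribute and were not separated, and no group received BTZ alone.

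The T cell list was higher in the anti-PDL1 than in the isotype tumours. Without isotype replicate 2 its median log2 fold change was 0.267 against 0.669 with it, and leaving out any other tumour gave 0.632 to 1.31, so few T cells in that 1 tumour may account for much of the size. Its depth of 20.97 M counts ranked 8 of 9 from the lowest, which argues against low depth. An effect of the antibody stays open.

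Each comparison of 3 tumours against 3 has 10 splits, too few for a share under 0.05. For anti-PDL1 against isotype 3 splits gave at least the 2 called genes (highest other 3) and 1 gave the 20 called lists (highest other 18). For BTZ+anti-PDL1 against anti-PDL1 1 split gave the 2 genes (highest other 1) and 4 gave at least 8 lists (highest other 13). For BTZ+anti-PDL1 against isotype 7 splits gave at least 1 gene (highest other 5) and 1 gave 20 lists (highest other 19).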
